A study of Homo sapiens with 8 samples.

How the data were processed

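RNA-seq gene counts of 8 libraries from the human lung adenocarcinoma line PC9, its brain metastatic subline PC9-BrM3 and PC9-BrM3 cells with an inducible shRNA were analysed. Groups came from the sample titles: PC9 parental, PC9-BrM3, shNTC (non-target hairpin) and shHSF1 (1 hairpin), 2 libraries each. Total RNA was taken with a column kit and libraries were prepared at a sequencing core, per the labels' protocols.

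The deposited values are raw read counts per gene. Per the file headers, the authors counted reads with featureCounts 1.6.1 over exons grouped by Ensembl gene ID, as reverse-stranded, with an Ensembl GRCh37 annotation. Trim Galore, HISAT2, featureCounts and DESeq2 with GRCh37 are named per the submitters' processing notes, with no version or role for the others. Counting by strand separates overlapping genes on opposite strands, while reads that map to several near-identical copies can be lost or uncertain. The files hold 63677 gene IDs, 5904 of them outside the primary chromosomes with 0 counts in total. Symbols were found for 52526 IDs (82.5%), and IDs without one held 0.57% to 0.74% of the counts of each library. Positions are those of the files (GRCh37, counted from 1). GC content and transcript length came from GENCODE v29 transcripts by gene ID only.

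Totals ran from 33550140 to 56715336 counts per library. Counting intervals are exact binomial 95% intervals and, like limits from a count of 0 (3 counts), cover counting error only. Replicate pairs differed by more than sampling noise in each group (chi-square per degree of freedom 25.1, 301, 24.2 and 10.9 for PC9 parental, PC9-BrM3, shNTC and shHSF1), so none was treated as a copy. The file headers name lane 7 for the untransduced and lane 1 for the transduced libraries. No gene-by-gene test of fold changes was run between those sets. The closing section uses ratios between them in its tests of HSF1 and of chromosome bins.

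Each comparison used its own 4 libraries in edgeR 4.0.16 (R 4.3.3): filterByExpr (minimum count 10, minimum total 15), TMM factors, and the quasi-likelihood F test with robust=TRUE, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 2 libraries per group the model has 2 residual degrees of freedom, to which empirical Bayes adds information shared across genes. Normalized counts are CPM on TMM-scaled library sizes. The 32 gene lists, written from textbook knowledge before the data were examined, were tested with camera (limma 3.58.1; preset correlation 0.01, at least 5 tested members), again with an estimated correlation, and with fry. With an estimated correlation 0 lists passed camera in either comparison. The smallest camera adjusted p was 0.485 in the knockdown and 0.627 in the subline comparison, with 2 and 0 lists at an unadjusted p under 0.05. That form rests on the 2 residual degrees of freedom, so few lists could pass whatever their correlation. The knockdown p53 list, with an estimated correlation of -0.011 against the preset 0.01, went from camera adjusted p = 0.000983 to 0.485. For that list the change does not come from a higher correlation. Estimated correlations ran from -0.121 to 0.925 in the knockdown and from -0.164 to 0.989 in the subline comparison. Where the estimate lies far above 0.01, as for knockdown G2/M (0.886) and E2F (0.607), the camera p-value rests on the preset. For such lists these values do not tell the few degrees of freedom from correlation between genes. Fry, which asks whether a list moves on balance 1 way without comparing it with other genes, passed 14 and 0 lists, and its mixed form, for change in either direction, 31 and 24. Its 14 knockdown lists are not those of camera: G2/M (fry adjusted p = 0.0621), NF-kB (0.0826) and ATF4 (0.17) did not pass fry, and the interferon, antigen presentation and fibroblast lists did. Histone symbols were matched for 15 of 26 listed genes. Overlap was tested with a two-sided Fisher's exact test over genes tested in both comparisons. This test counts genes as independent, which they are not.

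Named genes were chosen by a rule set before the data were examined: HSF1, ABL1 and ABL2; in each comparison the 8 largest rises and 8 largest falls with adjusted p under 0.05, at least 5 CPM in 1 group and non-overlapping replicates; up to 4 members of each called list by smallest p in its direction, and of the heat shock, E2F, G2/M and brain metastasis lists in both directions; and 5 genes per opposite direction past the threshold in both comparisons. Genes named outside it are marked as such, and FOS, DUSP6, ETV5, AREG, EGR1 and EGFR were also named after their values were seen.

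The test was tried on counts simulated 5 times from the means and library sizes of each comparison, with 200 genes changed each time. Each gene had its own dispersion, equal in both groups, so the larger spread of the PC9-BrM3 pair was not simulated. In the knockdown comparison (16569 to 16591 genes) 75.8%, 91.3% and 99.7% of genes changed 1.5-, 2- and 4-fold were recovered, and 11.4% of calls were of unchanged genes. In the subline comparison (17053 to 17068 genes) the values were 3.3%, 29% and 92.1%, with 13.3% of calls of unchanged genes. Both shares exceed the nominal 5%, while unchanged genes had an unadjusted p under 0.05 in 5% and 4.9% of cases. Such a share depends on how many genes change, so it need not hold where more genes pass. A list raised 1.5-fold was recovered by camera in each comparison, with 0 and 1 other lists called. The bin test of the closing section called 0 of 144 bins on shuffled genes and recovered 1 bin raised by 0.4. Shuffled genes are the same random genes that the test draws, so the first outcome was nearly given. It does not show how often neighbouring genes that move together for other reasons would be called.

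Alternatives were RLE and upper-quartile factors, no count filter, a stricter filter (1 CPM in 2 libraries and 30 counts), DESeq2 1.42.0, limma voom, all 8 libraries in 1 fit, a replicate block, robust=FALSE, other thresholds, and each library left out; a fit with 1 library left in a group assumes that it varies like the other group. Offsets for GC content and length and the removal of mitochondrial genes were added after seeing the data. Plots were drawn with matplotlib 3.10.9 (Python 3.11.15).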

Results

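RNA was sequenced from PC9, a human lung adenocarcinoma cell line that carries an activating EGFR mutation, and from PC9-BrM3, a brain metastatic subline of it. The 8 libraries fall into 4 groups of 2: PC9 parental, PC9-BrM3, PC9-BrM3 carrying a doxycycline-inducible non-target shRNA (shNTC), and PC9-BrM3 carrying an inducible shRNA against HSF1 (shHSF1, 1 hairpin). The transduced cells were selected in puromycin for 5 days and induced with doxycycline at 500 ng/mL for 48 h, and the untransduced cells were cultured for 48 h. Gene-assigned counts per library were 56715336 and 52112248 in PC9 parental, 52076511 and 39676578 in PC9-BrM3, 47450446 and 36281879 in shNTC, and 36695501 and 33550140 in shHSF1. A count of 0 in 1 library allows up to 0.0529 to 0.0894 CPM (counts scaled to library size), taking 3 counts as the limit. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The file headers place the 4 untransduced libraries on lane 7 and the 4 transduced ones on lane 1, so each comparison lies within 1 lane.

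HSF1, the transcription factor that drives the heat shock response, was measured in every library first, as a check of the labels. Its transcript (ENSG00000185122, chromosome 8 from 145515280 to 145538385 in GRCh37) was 12.2-fold lower in shHSF1 than in shNTC, a log2 fold change of -3.61 ± 0.08 (SE, n = 2 per group; edgeR quasi-likelihood adjusted p = 2.66e-08). On 1 scale for all libraries it stood at 181.1 ± 3.82 normalized CPM in shNTC and 14.5 ± 1.48 in shHSF1 (SD, n = 2 each). In untransduced cells it stood at 53.6 ± 1.33 in PC9-BrM3 and 48.5 ± 2.16 in PC9 parental, and these differed by a log2 fold change of 0.15 ± 0.14 (SE; edgeR adjusted p = 0.531). ABL2, a tyrosine kinase, was 3.23-fold higher with shHSF1 (log2 fold change 1.69 ± 0.09, SE; edgeR adjusted p = 5.02e-07), at 234.2 ± 26.9 normalized CPM against 73.6 ± 3.92 in shNTC (SD, n = 2 each). Its paralog ABL1 was 1.55-fold lower (log2 fold change -0.63 ± 0.07, SE; edgeR adjusted p = 4.24e-05), at 61.7 ± 0.93 against 96.9 ± 3.51. Between PC9-BrM3 and PC9 parental, ABL1 had a log2 fold change of -0.17 ± 0.15 and ABL2 of -0.34 ± 0.16 (SE), with edgeR adjusted p = 0.514 and 0.24. ABL1 (ENSG00000097007) and ABL2 (ENSG00000143322) are separate loci on chromosomes 9 and 1. Transduced and untransduced libraries lie on separate lanes, so levels may differ between them through the lane. The closing section gives a GC trend between the lanes.

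**Figure D1:**
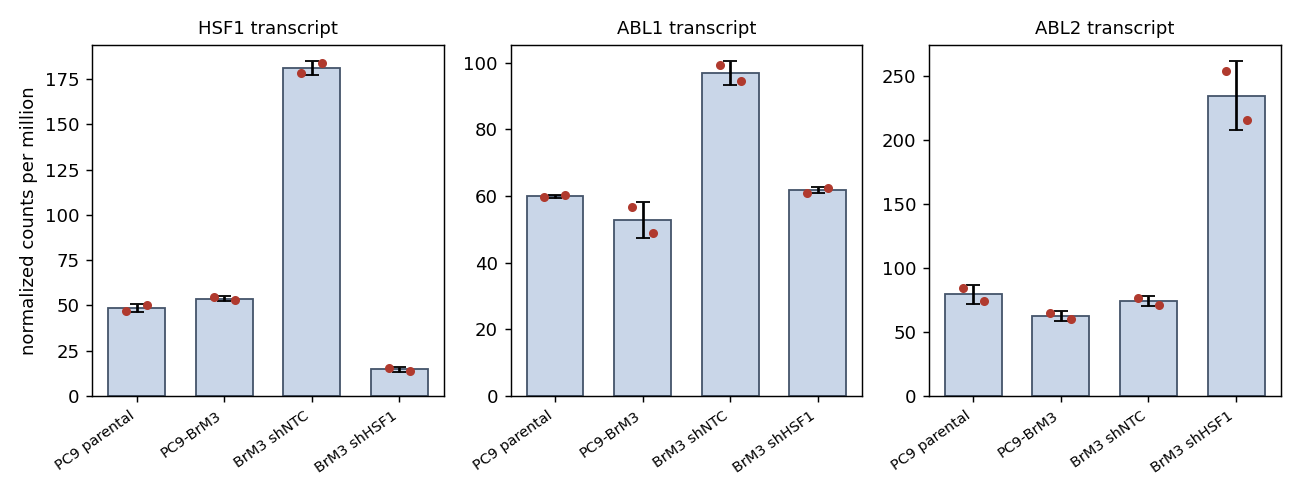
Normalized CPM (vertical axis) of HSF1, ABL1 and ABL2 in the 4 groups (horizontal axis); bars are group means, whiskers the SD of 2 libraries and points the libraries. HSF1 is 181.1 in shNTC and 14.5 in shHSF1, while both untransduced groups lie between these values. The untransduced and transduced groups lie on separate lanes, so differences between them may come from the lane.

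The knockdown comparison asks which transcripts differ with the HSF1 hairpin in the metastatic subline. Only 1 hairpin against HSF1 was used, so effects of losing HSF1 cannot be told apart from other effects of that hairpin. With shHSF1, 23 of 32 genes of a heat shock list (textbook HSF1 targets), 46 of 56 E2F and replication genes and 41 of 46 mitosis genes were lower than with shNTC. In turn, 21 of 25 cholesterol synthesis genes, 18 of 21 YAP and TAZ targets and 15 of 22 immediate early genes were higher. None of these lists passed with an estimated correlation (camera adjusted p = 0.578, 0.602, 0.602, 0.542, 0.485 and 0.485 with an estimated correlation). That form rests on 2 residual degrees of freedom and could pass few lists, so it does not decide. The estimated correlations were 0.283, 0.607, 0.886, 0.545, 0.533 and 0.017 in the same order, against the preset 0.01. The camera p-values below with the preset therefore rest on it, least so for the immediate early list. The largest rise was in TMEM52B, from 5 control counts, followed by OLR1, a scavenger receptor (63.9-fold), C4BPB, a complement regulator (44.6-fold), ROS1, a receptor tyrosine kinase (30.6-fold), LINC00707 (27.5-fold) and KRT17, a basal keratin (27.2-fold). The largest falls after HSF1 itself were in FKBP5, an immunophilin that binds HSP90 (10.5-fold), FAM30A (9.61-fold), PADI4, a protein arginine deiminase (9.27-fold), and GPR180 (9.06-fold). In all, 7701 of 16840 tested genes (45.7%) differed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 3739 higher and 3962 lower, and 1749 of them differed at least 2-fold, 857 higher and 892 lower. The balance of directions depended on scaling, with 4592 higher and 3387 lower under upper-quartile factors. In all 7701 the libraries of the groups did not overlap, which selection by p with 2 libraries per group nearly requires. Among all tested genes 73.3% did not overlap, where chance gives 33.3%.

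Log2 fold changes of the 8 largest rises began with TMEM52B, for which 5 counts in the shNTC libraries faced 521 in shHSF1, a ratio of 121 (95% counting interval 51.4 to 374). OLR1, which overlaps TMEM52B on the opposite strand of chromosome 12 and was counted by strand, rose 63.9-fold from 0.96 ± 0.25 to 62.6 ± 8.08 CPM (SD, n = 2 each; SE of its log2 fold change 0.16; edgeR adjusted p = 2.66e-08). C4BPB rose by 5.48 ± 0.27, ROS1 by 4.93 ± 0.54 (4.27 without shHSF1 replicate 1, 5.6 without shNTC replicate 1), LINC00707 by 4.78 ± 0.23, KRT17 by 4.77 ± 0.16, ACTBL2 by 4.25 ± 0.26 and EDN1, the precursor of the vasoconstrictor endothelin-1, by 4.11 ± 0.20, with edgeR adjusted p values of 0.000251 or less. FKBP5 had a log2 fold change of -3.39 ± 0.13 (SE; edgeR adjusted p = 1.1e-07), from 21.7 ± 0.59 to 2.07 ± 0.14 CPM (SD, n = 2 each). FAM30A had -3.27 ± 0.12, PADI4 -3.21 ± 0.16, GPR180 -3.18 ± 0.10, UBL4B -3.14 ± 0.18, PGRMC1, a heme-binding membrane protein, -2.98 ± 0.11 and SLC35A5 -2.95 ± 0.11, with edgeR adjusted p values of 9.26e-07 or less.

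Most members of the heat shock list are cytosolic chaperones and co-chaperones. It also holds SERPINH1, the mitochondrial HSPD1 and HSPE1, and RGS2, UBB and DEDD2, which are no chaperones. Of 32 tested members 23 fell and 3 rose (24 and 3 adjusted over the list alone), with a median log2 fold change of -0.58. The list passed camera (adjusted p = 1.27e-06), and gave adjusted p = 0.578 with an estimated correlation. SERPINH1, the collagen chaperone, had a log2 fold change of -1.90 ± 0.08, HSPA4L -1.42 ± 0.06, HSPH1, a nucleotide exchange factor of HSP70, -1.27 ± 0.07 and HSP90AA1, the inducible HSP90, -1.10 ± 0.07 (SE; edgeR adjusted p values of 1.24e-06 or less). HSP90AA1 dropped from 6843 ± 57.5 to 3184 ± 241 CPM (SD, n = 2 each). The 3 risers were HSPB8 (0.64 ± 0.13), HSPBP1 (0.41 ± 0.11) and DNAJB6 (0.35 ± 0.06), with edgeR adjusted p = 0.00306, 0.0167 and 0.00147. DNAJB6 lost its call with all 8 libraries in 1 fit (adjusted p = 0.124). The call of HSPBP1 was lost without shNTC replicate 2 (adjusted p = 0.0804) and without shHSF1 replicate 2 (0.0922, the largest over its alternatives). HSPA1A and HSPA1B are near-identical copies whose reads are uncertain.

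Of 56 tested E2F targets and DNA replication genes, 46 fell and 2 rose (47 and 2 adjusted over the list alone), with a median log2 fold change of -0.50 and adjusted p = 8.97e-11 by camera. The list gave adjusted p = 0.602 with an estimated correlation. MCM5, a subunit of the replicative helicase, had -1.33 ± 0.10, RAD51AP1, a recombination factor, -1.09 ± 0.08, RRM2, a ribonucleotide reductase subunit, -0.93 ± 0.07 and CHEK1, a checkpoint kinase, -0.80 ± 0.07 (SE; edgeR adjusted p values of 1e-05 or less). The 2 risers were CDC25A (0.37 ± 0.11, edgeR adjusted p = 0.0201) and CCNE1 (0.27 ± 0.10, edgeR adjusted p = 0.0494). Neither held in every leave-one-out fit, with the largest adjusted p at 0.163 for CDC25A and 0.334 for CCNE1, both without shHSF1 replicate 2. Of 46 G2/M and mitosis genes, 41 fell and 0 rose (42 and 0 adjusted over the list alone), with a median of -0.67 and adjusted p = 6.33e-16 by camera, and adjusted p = 0.602 with an estimated correlation. NCAPH, a condensin subunit, had -1.54 ± 0.09, NUSAP1, a spindle protein, -1.36 ± 0.08, KIF14, a mitotic kinesin, -1.37 ± 0.10 and ASPM, a spindle pole protein, -0.95 ± 0.07.

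Of 25 cholesterol synthesis genes, 21 rose and 1 fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 0.77 and adjusted p = 3.55e-12 by camera. This list gave adjusted p = 0.542 with an estimated correlation. MVD, mevalonate decarboxylase, rose by 1.13 ± 0.07, MSMO1 by 1.10 ± 0.07, ACAT2 by 0.99 ± 0.06 and LSS, lanosterol synthase, by 0.95 ± 0.06 (SE). Of 21 YAP and TAZ targets, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 1.01 and adjusted p = 5.38e-17 by camera, and adjusted p = 0.485 with an estimated correlation. Within it NUAK2 rose by 2.91 ± 0.15, CCN1, a matricellular protein, by 2.48 ± 0.11 and GADD45A by 1.85 ± 0.07. F3, the tissue factor gene, also rose, from 132.9 ± 12.6 to 751.1 ± 42.9 CPM (SD, n = 2 each).

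Of 22 immediate early stress genes, 15 rose and 2 fell (15 and 2 adjusted over the list alone; camera adjusted p = 4.39e-07), with adjusted p = 0.485 with an estimated correlation. DUSP1, a MAP kinase phosphatase, rose 10.3-fold (log2 fold change 3.37 ± 0.09, SE), ATF3 by 2.48 ± 0.21, PPP1R15A by 1.75 ± 0.07 and SGK1 by 1.27 ± 0.09 on the log2 scale. Replication-dependent histones held 8 higher and 1 lower of 13 tested members (8 and 2 adjusted over the list alone; camera adjusted p = 5.27e-05), and adjusted p = 0.485 with an estimated correlation. H2BC5 rose by 2.18 ± 0.13, H2AC6 by 2.00 ± 0.13, H2BC12 by 1.85 ± 0.10 and H1-2 by 1.53 ± 0.12, with the reads of such near-identical gene copies uncertain. NF-kB and inflammatory genes held 13 higher and 1 lower of 25 (17 and 1 adjusted over the list alone; camera adjusted p = 9.95e-05), with adjusted p = 0.602 with an estimated correlation. TNFAIP3, a feedback inhibitor of NF-kB, rose by 1.90 ± 0.13, BIRC3 by 1.79 ± 0.13, BCL3 by 1.38 ± 0.15 and NFKBIE by 1.37 ± 0.10.

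The mesenchymal list held 16 higher and 6 lower of 30 members (17 and 6 adjusted over the list alone; camera adjusted p = 0.000283), and adjusted p = 0.485 with an estimated correlation. MYL9, a myosin light chain, rose by 3.15 ± 0.22, TAGLN, an actin-binding protein, by 2.76 ± 0.17, AXL, a receptor tyrosine kinase, by 1.49 ± 0.08 and TGFBI by 0.82 ± 0.06. Members of the TGF-beta target list stood at 12 higher and 2 lower of 20 (12 and 3 adjusted over the list alone; camera adjusted p = 0.000338), with adjusted p = 0.485 with an estimated correlation. IL11 rose by 2.05 ± 0.15, SMAD7, an inhibitor of the pathway, by 1.53 ± 0.09 and COL1A1 by 1.18 ± 0.09. Receptor tyrosine kinases held 12 higher and 1 lower of 20 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000983), with adjusted p = 0.485 with an estimated correlation. EPHA2 rose by 0.68 ± 0.06, IGF1R by 0.66 ± 0.07 and ERBB3 by 0.55 ± 0.06, while EGFR itself had a log2 fold change of 0.09 and did not pass the test.

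Targets of p53 held 10 higher and 2 lower of 21 (10 and 2 adjusted over the list alone; camera adjusted p = 0.000983), and adjusted p = 0.485 with an estimated correlation. CDKN1A, a cyclin-dependent kinase inhibitor, rose by 1.66 ± 0.14, ZMAT3 by 0.87 ± 0.09 and CCNG1 by 0.71 ± 0.08. The list median was 0.21, and 0.34 without shNTC replicate 1. ATF4 and amino acid response genes held 12 higher and 4 lower of 30 (12 and 4 adjusted over the list alone; camera adjusted p = 0.0182), with adjusted p = 0.785 with an estimated correlation. SLC7A5, an amino acid transporter, rose by 1.21 ± 0.09, CTH by 0.97 ± 0.09 and TRIB3 by 0.89 ± 0.08. This list lost its call without shNTC replicate 2 (camera adjusted p = 0.112) and without shHSF1 replicate 1 (0.0658), and its median of 0.13 ran from -0.01 to 0.27 with 1 library left out. WNT and TCF targets held 6 higher and 2 lower of 14 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0482), with adjusted p = 0.542 with an estimated correlation. DKK1, a WNT antagonist, rose by 1.25 ± 0.07, HOXB9 by 1.17 ± 0.15, LEF1 by 1.06 ± 0.12 and SOX4 by 0.46 ± 0.09. The WNT list lost its call with a replicate block (camera adjusted p = 0.0527), without shNTC replicate 1 (median 0.29) and without shHSF1 replicate 2 (median 0.44).

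**Figure D2:**
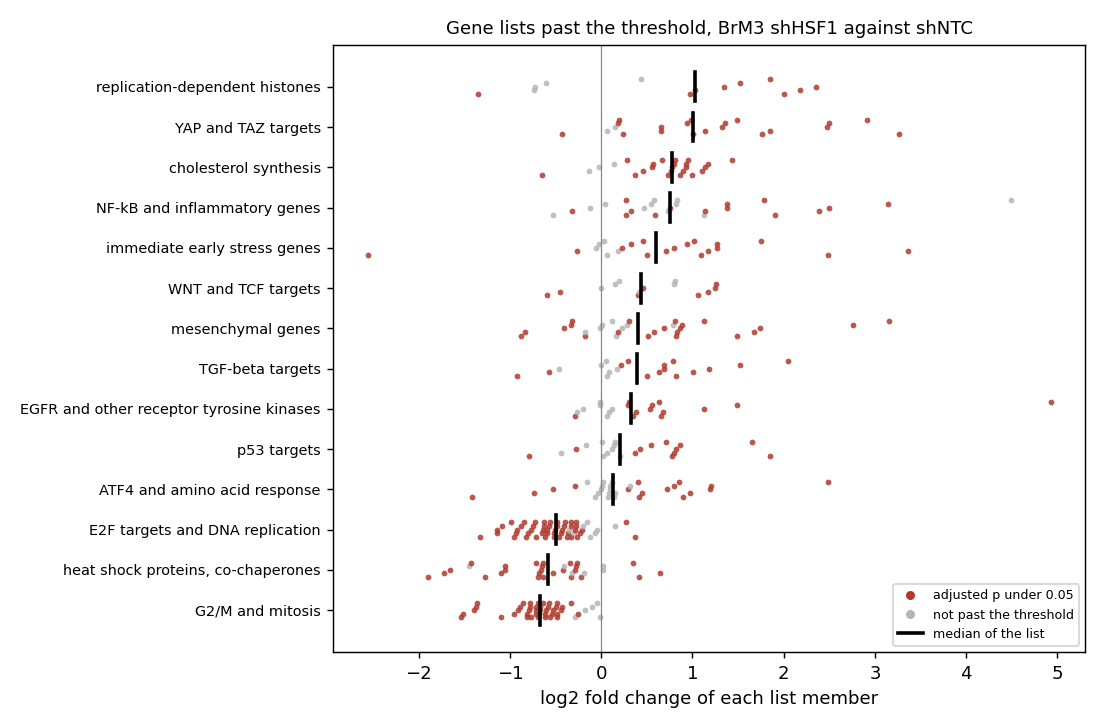
Log2 fold changes of list members, shHSF1 against shNTC (horizontal axis), for the 14 lists past the threshold by camera (vertical axis); red points are genes past an adjusted p of 0.05, grey points are not, and black lines are list medians. The G2/M median lies at -0.67 and the YAP and TAZ median at 1.01.

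Published mediators of lung and breast brain metastasis went both ways with shHSF1, 16 higher and 8 lower of 29 (17 and 9 adjusted over the list alone), and the list missed the threshold (camera adjusted p = 0.0514). L1CAM, a neural adhesion molecule, rose by 1.88 ± 0.11, ABL2 by 1.69 ± 0.09, AXL by 1.49 ± 0.08 and LAMC1, a laminin chain, by 0.81 ± 0.06 (SE). SERPIND1 had a log2 fold change of -2.66 ± 0.30, PLAT, the tissue plasminogen activator, of -2.36 ± 0.12, WWTR1, which encodes TAZ, of -0.64 ± 0.07 and ABL1 of -0.63 ± 0.07. It passed with a replicate block (camera adjusted p = 0.0309), no count filter (0.0168), GC and length offsets (0.043) and mitochondrial genes left out (0.0431). It also passed without shHSF1 replicate 1 (median 0.38) and without shHSF1 replicate 2 (median 0.36), against a median of 0.42. With an estimated correlation its camera adjusted p was 0.542. In the main fit the other lists did not pass either. Of the 14 tested subunits of the CCT chaperonin and prefoldin, 1 were higher and 5 lower, 1 and 5 adjusted over the list alone (adjusted p = 0.452 by camera). The 24 genes of the endoplasmic reticulum unfolded protein response held 10 higher and 5 lower members, 11 and 5 adjusted over the list alone, and camera gave adjusted p = 0.988. Among 30 proteasome subunits 14 were called higher and 2 lower, or 14 and 2 adjusted over the list alone, with adjusted p = 0.0652 for the list by camera. For the 27 NRF2 targets these counts were 7 and 8, or 7 and 8 adjusted over the list alone, at adjusted p = 0.452 by camera. Of the 34 tested hypoxia and glycolysis genes, 9 were higher and 15 lower, 9 and 17 adjusted over the list alone (adjusted p = 0.28 by camera). Among 44 nuclear-encoded oxidative phosphorylation genes 17 were called higher and 0 lower, or 15 and 0 adjusted over the list alone, with adjusted p = 0.0559 for the list by camera. For the 31 epithelial genes these counts were 13 and 9, or 13 and 9 adjusted over the list alone, at adjusted p = 0.345 by camera. The 26 genes of MAPK pathway output held 10 higher and 9 lower members, 10 and 10 adjusted over the list alone, and camera gave adjusted p = 0.355. Of the 34 tested interferon-stimulated genes, 3 were higher and 14 lower, 3 and 14 adjusted over the list alone (adjusted p = 0.0914 by camera). Among 16 antigen presentation genes 7 were called higher and 3 lower, or 7 and 3 adjusted over the list alone, with adjusted p = 0.203 for the list by camera. The 10 lung lineage and surfactant genes held 0 higher and 6 lower members, 0 and 6 adjusted over the list alone, and camera gave adjusted p = 0.122. For the 9 neural and brain cell markers these counts were 4 and 3, or 4 and 3 adjusted over the list alone, at adjusted p = 0.433 by camera. Of the 7 tested immune cell markers, 1 were higher and 2 lower, 1 and 2 adjusted over the list alone (adjusted p = 0.753 by camera). Among 8 fibroblast and endothelial markers 4 were called higher and 2 lower, or 4 and 2 adjusted over the list alone, with adjusted p = 0.371 for the list by camera. For the 53 ribosomal protein genes these counts were 7 and 3, or 6 and 3 adjusted over the list alone, at adjusted p = 0.433 by camera. The 37 ribosome biogenesis and MYC targets held 6 higher and 12 lower members, 6 and 12 adjusted over the list alone, and camera gave adjusted p = 0.203. Of the 15 tested mitochondrial genome transcripts, 0 were higher and 1 lower, 0 and 0 adjusted over the list alone (adjusted p = 0.433 by camera). For the unfolded protein response the median (0.16) and mean (-0.01) had opposite signs, as did those of MAPK output (0.12 and -0.11), where FOS, DUSP6 and ETV5 were lower and AREG and EGR1 higher.

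In fitting all 8 libraries together, with spread shared with the PC9-BrM3 pair, 3931 genes passed in the knockdown comparison in place of 7701. In simulated libraries with this comparison's spread, 11.4% of calls were of unchanged genes.

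The subline comparison asks which transcripts differ in the brain metastatic derivative. In PC9-BrM3, L1CAM, a neural adhesion molecule, was 44.3-fold higher than in PC9 parental, and the long noncoding RNA H19 and the interferon-induced BST2 (tetherin) were 195-fold and 30.8-fold higher (H19 by a log2 fold change of 6.91 in place of 7.61 without PC9-BrM3 replicate 2). GABRE, a GABA receptor subunit, and CDH13, an atypical cadherin, were close to undetected in PC9-BrM3. Of 30 genes of the ATF4 amino acid response 13 were lower, 1 was higher and 16 did not pass, and the list gave adjusted p = 0.627 with an estimated correlation. In all, 1240 of 17372 tested genes (7.1%) passed edgeR's quasi-likelihood test at an adjusted p under 0.05, 672 higher and 568 lower, and 1032 of them differed at least 2-fold, 569 higher and 463 lower. The 2 PC9-BrM3 libraries differed from each other more than other pairs: the SD of their log2 ratio over genes was 0.494, against 0.168 to 0.171 in the other pairs, and mitochondrial transcripts held 17.29% of counts in replicate 2 and 5.4% in replicate 1.

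Counts of GGT6, a gamma-glutamyltransferase family member, were 5 in PC9 parental and 1201 in PC9-BrM3, a ratio of 304 (95% counting interval 130 to 937). H19 (chromosome 11) had a log2 fold change of 7.61 ± 0.52, from 10.3 ± 2.27 to 2014 ± 1068 CPM (SE of the fold change; SD, n = 2 each; edgeR adjusted p = 0.00349). FOXI1, a forkhead factor of ionocytes, had 6.11 ± 0.37, IGFBP5 5.91 ± 0.31, L1CAM 5.47 ± 0.18, BST2 4.95 ± 0.33 and MYLK, myosin light chain kinase, 4.70 ± 0.32 (SE; edgeR adjusted p values of 0.00344 or less). MUC6, a gastric mucin, had 6.21 ± 0.95 (edgeR adjusted p = 0.0221) but stood at 202.4 ± 207.3 CPM in PC9-BrM3 (SD, n = 2). Its log2 fold change was 6.99 without PC9-BrM3 replicate 1 and 4.33 without replicate 2. The call of MUC6 was lost without PC9 parental replicate 1 (adjusted p = 0.305) and without PC9 parental replicate 2 (0.608), the largest over its alternatives.

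GABRE went from 69.7 ± 22.9 CPM to 1 count in the PC9-BrM3 libraries, a ratio of 6300 (95% counting interval 1130 to 249000), with edgeR adjusted p = 0.00189. Without PC9-BrM3 replicate 1 its adjusted p was 0.0655, and without replicate 2 it was 0.0808, the largest over its alternatives. CDH13 went from 2373 counts to 1, a ratio of 1880 (336 to 74200; edgeR adjusted p = 0.00156). CA12, a carbonic anhydrase, and KCNQ3, a potassium channel, had 0 counts in both PC9-BrM3 libraries and were at least 172-fold and at least 166-fold lower, taking 3 counts over the group as the limit. FAM167A had a log2 fold change of -7.85 ± 0.36, CHRDL1, a BMP antagonist, of -7.38 ± 0.49, AGPAT4 of -6.99 ± 0.46 and UGT8, which makes galactocerebroside, of -6.98 ± 0.41 (SE; edgeR adjusted p values of 0.00344 or less), with 4 to 9 counts each in PC9-BrM3. Without PC9-BrM3 replicate 1 the values of FAM167A, CHRDL1 and AGPAT4 were -8.6, -6.48 and -6.25, and without replicate 2 those of CHRDL1 and AGPAT4 were -8.63 and -7.88.

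Of 30 ATF4 and amino acid response genes, 13 fell and 1 rose (24 and 2 adjusted over the list alone), with a median log2 fold change of -0.99 and adjusted p = 7.62e-12 by camera. The list gave adjusted p = 0.627 with an estimated correlation. DDIT4, an inhibitor of mTORC1, had -2.43 ± 0.25, ASNS, asparagine synthetase, -2.10 ± 0.24, CTH -1.72 ± 0.14 and SLC7A11, the cystine transporter, -1.60 ± 0.17 (SE; edgeR adjusted p values of 0.0106 or less). DDIT4 went from 229.9 ± 41.1 to 42.8 ± 11.1 CPM (SD, n = 2 each). The riser was NUPR1, a stress-responsive chromatin protein, with a log2 fold change of 3.90, named after its value was seen. Without PC9-BrM3 replicate 2 the list kept its direction, at a median of -0.81 (camera adjusted p = 5.78e-15). Of 53 ribosomal protein genes none passed singly (0 higher, 0 lower; 0 and 0 adjusted over the list alone), but the median was -0.64 and camera gave adjusted p = 5.97e-09, with adjusted p = 0.627 with an estimated correlation. Ribosomal protein genes also differed between the PC9-BrM3 libraries, by a median of -0.52 in replicate 2 against replicate 1, and the list median was -0.40 without replicate 2 (camera adjusted p = 2.26e-09) and -0.97 without replicate 1.

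Of 56 E2F targets and DNA replication genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.31 and adjusted p = 0.00243 by camera, and adjusted p = 0.627 with an estimated correlation. MYBL2, a cell cycle transcription factor, had 1.41 ± 0.24, CCNE2, a cyclin, 1.34 ± 0.20, E2F8 1.23 ± 0.18 and E2F7 1.07 ± 0.18 (SE), and each lost its call when either PC9 parental library was left out, with adjusted p up to 0.353. Of 46 G2/M and mitosis genes, 1 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.21 and adjusted p = 0.033 by camera, and adjusted p = 0.683 with an estimated correlation. NCAPG rose by 0.72 ± 0.14, which did not hold without PC9 parental replicate 1 (adjusted p = 0.489) or replicate 2 (0.559). Without PC9-BrM3 replicate 2 the G2/M list had camera adjusted p = 0.0521, and without PC9 parental replicate 2 it had 0.0836.

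Interferon-stimulated genes held 7 higher and 0 lower of 35 (9 and 1 adjusted over the list alone; median 0.33; camera adjusted p = 0.0032), with adjusted p = 0.627 with an estimated correlation. Their median was 0.15 without PC9-BrM3 replicate 2 and 0.21 without PC9 parental replicate 1. XAF1, an inhibitor of XIAP, went from 3 counts to 365, a ratio of 154 (95% counting interval 52.2 to 750; edgeR adjusted p = 0.00622; log2 fold change 7.25, and 6.62 without PC9-BrM3 replicate 2), and BST2 rose 30.8-fold. OAS3, an RNA sensor, rose by 1.35 ± 0.16 and EPSTI1 by 2.67 ± 0.51, and both lost their calls without either PC9 parental library, with adjusted p up to 0.347. YAP and TAZ targets held 3 higher and 0 lower of 21 (6 and 3 adjusted over the list alone; median 0.32; camera adjusted p = 0.0134), with adjusted p = 0.627 with an estimated correlation. Without PC9-BrM3 replicate 2 the median of these targets was 0.17. ANKRD1 rose by 3.13 ± 0.26, IGFBP3 by 1.81 ± 0.24 and NUAK2 by 1.30 ± 0.25. IGFBP3 lost its call without either PC9-BrM3 library (adjusted p = 0.0608 and 0.0951) and NUAK2 without either PC9 parental library (0.394 and 0.422). Neural and brain cell markers held 3 higher and 1 lower of 11 (5 and 3 adjusted over the list alone; median 0.39; camera adjusted p = 0.0144), with adjusted p = 0.627 with an estimated correlation. Beside L1CAM the risers were SLC1A2, a glutamate transporter (2.13 ± 0.40), and ALDH1L1 (1.52 ± 0.23), both lost without PC9 parental replicate 1 (adjusted p = 0.215 and 0.117), and SLC1A2 also without replicate 2 (0.295). The list itself lost its call without PC9 parental replicate 1 (camera adjusted p = 0.111) and with no count filter (0.106, median -0.02), and its median was -0.06 without PC9-BrM3 replicate 1. The member that fell was SOX2, a stem cell factor, with a log2 fold change of -5.48, named after its value was seen.

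Published mediators of brain metastasis held 7 lower and 1 higher of 27 (10 and 4 adjusted over the list alone; median -0.36; camera adjusted p = 0.0188), with adjusted p = 0.627 with an estimated correlation. L1CAM was the riser, while ITGB3, an integrin, had -2.79 ± 0.25, SERPIND1 -2.12 ± 0.27, HOXB9 -2.09 ± 0.32 and HBEGF, a ligand of EGFR, -1.71 ± 0.17 (SE). HOXB9 lost its call without PC9 parental replicate 1 (adjusted p = 0.054), and the list lost its call without PC9-BrM3 replicate 1 (camera adjusted p = 0.17). Replication-dependent histones held 2 higher and 0 lower of 13 (6 and 0 adjusted over the list alone; median 0.60; camera adjusted p = 0.00311), with adjusted p = 0.627 with an estimated correlation. H1-3 rose by 2.21 ± 0.34 and H2BC4 by 1.86 ± 0.39, neither of which held without PC9 parental replicate 1 (adjusted p = 0.175 and 0.501), and the list did not hold without PC9-BrM3 replicate 1 (camera adjusted p = 0.0781) and had a median of 1.02 without PC9 parental replicate 2. Mitochondrial genome transcripts had a median of 1.26, with 0 of 15 past the test in either direction (0 and 0 adjusted over the list alone; camera adjusted p = 0.0134) and adjusted p = 0.786 with an estimated correlation. Without PC9-BrM3 replicate 2 that median was 0.09 (camera adjusted p = 0.921).

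Cholesterol synthesis genes held 0 higher and 1 lower of 25 (1 and 2 adjusted over the list alone; median -0.35; camera adjusted p = 0.0134), with adjusted p = 0.786 with an estimated correlation. NSDHL, a sterol enzyme, had -0.73 ± 0.15 (SE) and the list had camera adjusted p = 0.0759 without PC9 parental replicate 2. Oxidative phosphorylation genes held 0 higher and 1 lower of 44 (0 and 0 adjusted over the list alone; median -0.30; camera adjusted p = 0.033), with adjusted p = 0.786 with an estimated correlation. COX5A, a cytochrome oxidase subunit, had -0.85 ± 0.17, and the list had camera adjusted p = 0.429 and a median of -0.12 without PC9-BrM3 replicate 2. Without replicate 1 the median was -0.57, and with GC and length offsets it was -0.18 (camera adjusted p = 0.0525). Ribosome biogenesis and MYC targets held 0 higher and 1 lower of 37 (0 and 0 adjusted over the list alone; median -0.25; camera adjusted p = 0.0249), with adjusted p = 0.627 with an estimated correlation. CAD, an enzyme of pyrimidine synthesis, had -0.81 ± 0.16. The calls of NSDHL, COX5A and CAD were all lost without PC9 parental replicate 1 (adjusted p = 0.311, 0.325 and 0.293) and without replicate 2 (0.577, 0.368 and 0.414).

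**Figure D3:**
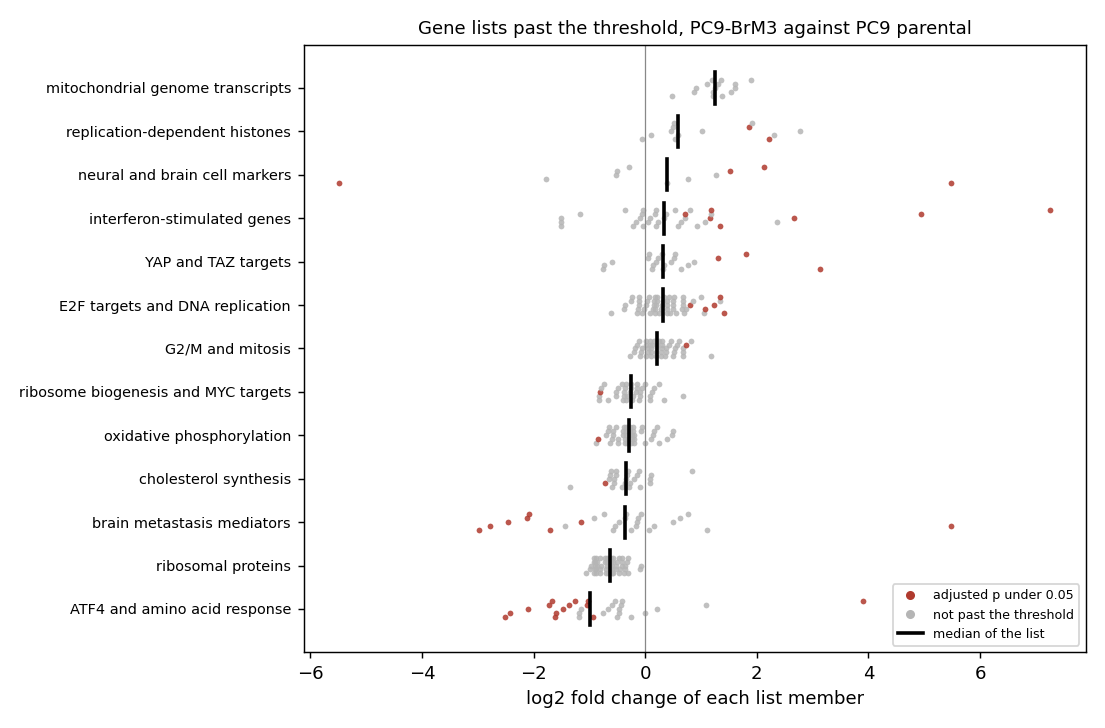
Log2 fold changes of list members, PC9-BrM3 against PC9 parental (horizontal axis), for the 13 lists past the threshold by camera (vertical axis); red points are genes past an adjusted p of 0.05, grey points are not, and black lines are list medians. The ATF4 list has its median at -0.99 with 13 members lower, and no ribosomal protein gene passed singly.

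Among the lists without a call, members of the heat shock list named by the rule were HSPB8, with 2.89 ± 0.19, and CRYAB, a small heat shock protein, with 3.17 ± 0.52, both higher, and RGS2, a regulator of G-protein signalling and no chaperone, with -3.08 ± 0.46 (SE). CRYAB lost its call without PC9 parental replicate 2 (adjusted p = 0.102) and stood at 3.78 without replicate 1. RGS2 lost its call with GC and length offsets (0.0514) and stood at -2.49 without PC9-BrM3 replicate 1 and -3.81 without replicate 2. Of the 33 tested genes of the heat shock list, 2 were higher and 1 lower, 2 and 1 adjusted over the list alone (adjusted p = 0.337 by camera). Among 14 subunits of the CCT chaperonin and prefoldin 0 were called higher and 0 lower, or 0 and 0 adjusted over the list alone, with adjusted p = 0.234 for the list by camera. For the 22 p53 targets these counts were 1 and 3, or 1 and 4 adjusted over the list alone, at adjusted p = 0.438 by camera. The 24 genes of the endoplasmic reticulum unfolded protein response held 0 higher and 1 lower members, 0 and 0 adjusted over the list alone, and camera gave adjusted p = 0.118. Among 30 proteasome subunits 0 were called higher and 0 lower, or 0 and 0 adjusted over the list alone, with adjusted p = 0.546 for the list by camera. For the 26 NRF2 targets these counts were 1 and 2, or 1 and 3 adjusted over the list alone, at adjusted p = 0.416 by camera. The 35 hypoxia and glycolysis genes held 1 higher and 3 lower members, 3 and 5 adjusted over the list alone, and camera gave adjusted p = 0.194. Among 31 epithelial genes 3 were called higher and 1 lower, or 3 and 1 adjusted over the list alone, with adjusted p = 0.09 for the list by camera. For the 31 mesenchymal genes these counts were 2 and 6, or 8 and 9 adjusted over the list alone, at adjusted p = 0.357 by camera. The 25 genes of MAPK pathway output held 0 higher and 3 lower members, 1 and 3 adjusted over the list alone, and camera gave adjusted p = 0.112. Among 19 receptor tyrosine kinases 1 were called higher and 0 lower, or 2 and 3 adjusted over the list alone, with adjusted p = 0.978 for the list by camera. For the 13 WNT and TCF targets these counts were 2 and 1, or 3 and 1 adjusted over the list alone, at adjusted p = 0.234 by camera. The 24 NF-kB and inflammatory genes held 4 higher and 2 lower members, 4 and 2 adjusted over the list alone, and camera gave adjusted p = 0.194. Among 17 antigen presentation genes 0 were called higher and 0 lower, or 0 and 0 adjusted over the list alone, with adjusted p = 0.281 for the list by camera. For the 20 TGF-beta targets these counts were 1 and 4, or 3 and 5 adjusted over the list alone, at adjusted p = 0.357 by camera. The 12 lung lineage and surfactant genes held 1 higher and 2 lower members, 2 and 4 adjusted over the list alone, and camera gave adjusted p = 0.166. Among 7 immune cell markers 2 were called higher and 0 lower, or 2 and 0 adjusted over the list alone, with adjusted p = 0.19 for the list by camera. For the 7 fibroblast and endothelial markers these counts were 0 and 1, or 0 and 1 adjusted over the list alone, at adjusted p = 0.771 by camera. The 24 immediate early stress genes held 2 higher and 1 lower members, 5 and 2 adjusted over the list alone, and camera gave adjusted p = 0.58. Median and mean differed in sign for mesenchymal genes (0.06 and -0.11), receptor tyrosine kinases (-0.06 and 0.05) and fibroblast and endothelial markers (0.10 and -0.10).

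Left-out libraries moved the number of subline calls from 1240 to 402 without PC9 parental replicate 1, 479 without PC9 parental replicate 2, 9228 without PC9-BrM3 replicate 1 and 5594 without PC9-BrM3 replicate 2. These counts follow the pair that alone sets the spread. Without a PC9-BrM3 library this is the PC9 parental pair (SD of its log2 ratio 0.169), otherwise the PC9-BrM3 pair (0.494). They, and the calls of named genes lost without a PC9 parental library, do not measure the stability of a fold change. Without PC9 parental replicate 1 and 2, MYBL2 had a log2 fold change of 1.35 and 1.43, and EPSTI1 3.15 and 2.3. In simulated libraries with 1 dispersion per gene for both groups, 3.3% of genes changed 1.5-fold and 92.1% of those changed 4-fold were recovered. There 13.3% of calls were of unchanged genes. The larger spread of the PC9-BrM3 pair than of the PC9 parental pair was not simulated, so these shares need not hold here.

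Whether genes that differ in the brain metastatic subline also move with HSF1 knockdown was asked over the 16201 genes tested in both comparisons, which share no library. APOBEC3G, a cytidine deaminase, was 17.7-fold higher in PC9-BrM3 and 4.17-fold lower with shHSF1, and ANXA1, a phospholipid-binding protein, was 11.1-fold lower in PC9-BrM3 and 3.42-fold higher with shHSF1. Fisher's exact test counts genes, which are not independent replicates, so its p-values and intervals here do not measure the spread between samples. Of 661 genes past the threshold in both, 369 (55.8%) went in opposite directions and 292 in the same one (odds ratio 1.6, 95% interval 1.16 to 2.21, Fisher's exact p = 0.00352). This excess was not seen with all 8 libraries in 1 fit (51.4% opposite, odds ratio 1.1, Fisher's exact p = 0.425) or without PC9-BrM3 replicate 2 (51.1%, odds ratio 1.1, p = 0.222). Genes higher in PC9-BrM3 and lower with shHSF1 numbered 213 where independent lists give 150.6 (odds ratio 1.67, 1.4 to 1.98; Fisher's exact adjusted p = 1.72e-08), and those lower in PC9-BrM3 and higher with shHSF1 numbered 156 where 102.6 are given (odds ratio 1.82, 1.48 to 2.22; adjusted p = 1.72e-08). Without PC9-BrM3 replicate 1 the latter odds ratio was 1.17. Of genes called in the subline comparison 60.8% were also called in the knockdown in either direction, against 46.2% of all 16201 genes. The excess over independent lists in each pair of directions includes this general excess. The 170 genes higher in both also exceeded 135.4 (odds ratio 1.37, 1.14 to 1.65; adjusted p = 0.00117), but not past the threshold with upper-quartile factors (1.18, Fisher's exact p = 0.0695) or without PC9 parental replicate 2 (1.31, p = 0.0786). The 122 lower in both did not pass against 114.1 (odds ratio 1.1, 0.882 to 1.36; Fisher's exact adjusted p = 0.383), yet passed with no count filter (1.71, p = 7.8e-16), with all 8 libraries in 1 fit (1.43, p = 2.37e-07) and without PC9-BrM3 replicate 2 (1.3, p = 4.26e-08).

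Other genes that rose in PC9-BrM3 and fell with shHSF1 were CASP14, a caspase of keratinocytes (4.87-fold and 6.16-fold), CAPN5, a calpain (4.13-fold and 4.69-fold), CST1, a cystatin (4.22-fold and 4.83-fold), and ADCY5, an adenylyl cyclase (4.12-fold and 4.11-fold). Those that fell in PC9-BrM3 and rose with shHSF1 were RAB3B, a vesicle GTPase (4.51-fold and 4.63-fold), COL4A6, a collagen chain (4.22-fold and 2.82-fold), AOX1, aldehyde oxidase (4.19-fold and 3.0-fold), and IL1R2, a decoy receptor (3.94-fold and 2.84-fold). In the subline comparison, the log2 fold change of CASP14 was 2.28 ± 0.43 and of APOBEC3G 4.15 ± 0.24 (SE; edgeR adjusted p = 0.0372 and 0.00239). CASP14 had 1.55 without PC9-BrM3 replicate 2 and lost that call without PC9 parental replicate 1 (0.116), with no count filter (0.117) and with GC and length offsets (0.0668), COL4A6 without PC9 parental replicate 2 (0.0717), and ANXA1 lost its knockdown call without either shHSF1 library (0.0756 and 0.0752). Reads of CST1 can be shared with near-identical cystatin genes. Across genes, which are not independent replicates, the log2 fold changes had Pearson's r = -0.028 and Spearman's rho = -0.039.

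**Figure D4:**
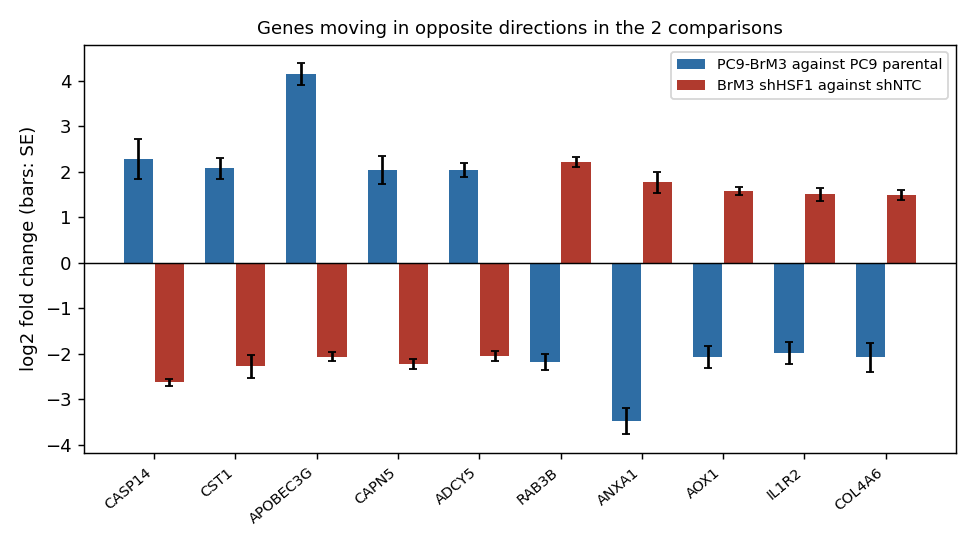
Log2 fold change with its SE (vertical axis) of the 10 genes named for opposite directions (horizontal axis), in PC9-BrM3 against PC9 parental (blue) and shHSF1 against shNTC (red). APOBEC3G stands at 4.15 and -2.06, and ANXA1 at -3.48 and 1.78.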

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

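The fits with GC and length offsets and without mitochondrial genes were chosen after seeing the data; other alternatives were set before. HSF1 kept its fall with shHSF1 under every alternative run. The knockdown count of 7701 genes became 3931 with all 8 libraries in 1 fit and 1749 with an absolute log2 fold change of at least 1, and leaving out libraries gave 6044 to 6514; the cause of the first was not tested. Upper-quartile factors turned the balance of knockdown calls from 48.6% to 57.6% higher, at a median log2 fold change of all genes of 0.074 against 0.006. The subline count of 1240 became 3159 with no count filter, 2203 with DESeq2, 3834 with all 8 libraries in 1 fit and 240 at an adjusted p under 0.01 (the cause was not tested for the first 3), and 402 to 9228 when 1 library was left out; the largest counts came without a PC9-BrM3 library, where the spread between the 2 PC9-BrM3 libraries no longer enters. With GC and length offsets 870 genes passed, at a median log2 fold change of all genes of 0.106 against 0.013, and 68.1% of the 1240 were kept, with 9 of 55 named calls lost (RGS2, MYBL2, NCAPG, NSDHL, COX5A, HOXB9, NUAK2, H2BC4 and CASP14); in the knockdown comparison 3 of 7701 genes changed sign. The replicate block gave 8015 and 1328 genes. Deviations of libraries with the same number correlated at 0.03 and -0.014 across genes over 2 pairs, which shows no sign of pairing. With 2 libraries per group this cannot exclude it. Both overlaps in opposite directions stayed past the threshold under every alternative run, with odds ratios of 1.45 to 2.19 (higher in PC9-BrM3) and 1.17 to 2.07 (lower in PC9-BrM3) with 1 library left out. The share of opposite directions among genes called in both, 55.8%, was 51.4% with all 8 libraries in 1 fit and 51.1% without PC9-BrM3 replicate 2, neither past the threshold. The odds ratio of genes higher in both fell to 1.18 with upper-quartile factors, past the threshold no longer, and ran from 1.13 to 1.57 with 1 library left out, losing the call without PC9 parental replicate 2 (1.31, Fisher's exact p = 0.0786). That of genes lower in both became 1.71 with no count filter and 1.43 with all 8 libraries, both past the threshold, 0.902 at an adjusted p under 0.01, where its direction reversed, and 1.01 to 1.3 with 1 library left out, past the threshold without PC9-BrM3 replicate 2; the cause was not tested. Pearson's r of -0.028 ran from -0.05 to -0.007 with 1 library left out. With an estimated correlation 0 of the 14 knockdown lists and 0 of the 13 subline lists passed, in a form with 2 residual degrees of freedom that could pass few lists. The block ended the calls of the WNT list (camera adjusted p = 0.0527), HSPBP1 (adjusted p = 0.0772), NCAPG (0.0619), NSDHL (0.0666) and H2BC4 (0.0521), and gave calls to the knockdown brain metastasis list (0.0309) and the subline epithelial list (0.0498); it changed no other call of a list or named gene. Lists without a call that passed under some alternative were proteasome, oxidative phosphorylation, interferon, lung, mitochondrial and brain metastasis genes in the knockdown comparison, and epithelial, MAPK, unfolded protein response, hypoxia, NRF2 and proteasome genes in the subline comparison. Of named genes, 84 of 89 in the knockdown and 33 of 58 in the subline comparison kept direction and side of the threshold throughout. Of them 0 reversed, and 5 and 23 lost a call. Most of the latter were lost without a PC9 parental library, where the PC9-BrM3 pair alone sets the spread. Depth limits genes near 0: 3 counts equal 0.0529 to 0.0894 CPM.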

Other observations

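Some genes were on in PC9 parental and near 0 in PC9-BrM3. With limits chosen after the values were seen (at least 5 normalized CPM in PC9 parental and under 0.2 in both PC9-BrM3 libraries), 15 genes, 13 with a symbol, met this, and 2, GGT6 and FOXI1, met the reverse. The transduced PC9-BrM3 cells, sequenced on the other lane, split these 15. In 6, among them GABRE, CDH13, CA12 and KCNQ3, every transduced library stayed under 0.2 CPM, as for CDH13 at 21.9 CPM in PC9 parental and 0.0136 in shNTC. In another 6 (COL8A1, KLF12, CNTN1, UGT8, FAM167A and CHRDL1) shNTC was above 1 CPM. COL8A1, a collagen chain, had 5.11 CPM in PC9 parental, 0.00939 in PC9-BrM3, 5.06 in shNTC and 7.4 in shHSF1, and KLF12 had 5.74, 0.062, 3.27 and 5.51. GGT6 had 13.4 CPM in PC9-BrM3 but 1.76 in shNTC, and FOXI1 7.16 and 0.352. These differences lie across lanes and were not tested.

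The tests below on the PC9-BrM3 libraries and on chromosome bins were chosen after their results were seen; the test on HSF1 was set before its result. The PC9-BrM3 libraries stood apart from each other, with an SD of the log2 ratio over genes of 0.494 against at most 0.171 in other pairs. Removing a smooth trend on GC content and length left 0.476, above 1.5 times the largest of the other pairs (0.256), which argues against that trend as the whole cause. Leaving out mitochondrial genes left 0.491, but reads lost to them would lower other genes alike and could not move this SD, so the test had only this outcome and is set aside. A difference between cultures or in RNA quality stays open, and no biological explanation was tested, since the design gives no group within PC9-BrM3.

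HSF1 was 3.38-fold higher in shNTC than in untransduced PC9-BrM3. The log2 ratios of shNTC to PC9-BrM3 correlated with GC content across 11734 genes (Spearman's rho 0.56), and HSF1 has 64.7% GC against a median of 48%. Among the 200 genes nearest to it in GC content, length and level, the HSF1 log2 ratio of 1.74 lay at the 76.5th percentile. The central 95% of these genes ran from -0.38 to 2.93, with a median of 1.15. A range this wide would admit most ratios, so the test cannot decide. A GC trend between the lanes stays a candidate explanation. Transduction, puromycin, doxycycline and the lane cannot be told apart here. The 31 heat shock genes had a median log2 ratio of 0.06 between the same groups.

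Genes of some chromosome regions shifted together between PC9-BrM3 and PC9 parental: 32 of 144 bins of 20 Mb with at least 25 genes had a median log2 ratio apart from random genes (10000 draws, adjusted p under 0.05), and after correction for GC content and length 21 kept their direction and call (median absolute shift 0.257 before, 0.243 after), which argues against that trend as the cause in these. The strongest lay on chromosome 15 from 80000001 to 100000000 (-0.53 after correction), followed by chromosome 3 from 120000001 to 140000000 and chromosome 4 from 1 to 20000000 (0.35 each), in GRCh37. In the other 11 bins the median absolute shift was 0.179 before and 0.137 after, and the calls ended as the shifts shrank, so for these the trend stays open. A regional difference such as copy number, kept by the transduced cells, may lie behind the shifts: of 24 bins called against PC9 parental replicate 1 alone, 19 (79.2%) had the same sign in shNTC against PC9 parental replicate 2, under the 80% set for the test, but so did 76 of 120 bins not called (63.3%; Fisher's exact p = 0.16 between these shares), so this stays open. DNA was not measured, so this remains a hypothesis.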
